A study of Mus musculus with 40 samples.

How the data were processed

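Liver and gonadal white adipose tissue of male and female C57BL/6J offspring were sampled after paternal nicotine or control exposure. The labels assign 40 samples to 8 groups of 5 by tissue, sex and exposure, and the 39 library columns of 4 tables, 1 table per tissue and sex, were analysed. The 4 control columns of the male gWAT table were treated as unnumbered control replicates, because the column names do not show which of the 5 labelled samples each one is. The column name DMSO was read as the labels' control. Per the labels' protocols, RNA was purified with Zymo Direct-zol columns and 3′-tag libraries were made with an Illumina kit. The submitters' processing notes name cutadapt, STAR, DESeq2 and the mm10 genome, without versions; the counting step, the annotation release, the use of strand and the gene filter are not given in the sources used here. Without stated strand use, reads of overlapping genes on opposite strands cannot be told apart.

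The deposited values are normalized counts, a signal made by the authors by dividing gene read counts by 1 DESeq2 size factor per library within each table, so values were compared only within a table. Per the file headers, each table also holds the authors' mean normalized count, log2 fold change (nicotine over DMSO) with its standard error, and p-value and adjusted p-value; whether the log2 fold change was shrunken is not stated. Whole reads were recovered from the normalized counts by finding the value of 1 read in each column: 100% of values came out whole within 0.1 reads in every library. The smallest total of a gene was 10 reads in each table. Depth ranged from 1543208 to 2239073 reads per library, and intervals and floors cover counting error only. The tables hold 14781 (female liver), 14591 (male liver), 17140 (female gWAT) and 18224 (male gWAT) genes.

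The following was computed here with R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The main test, the designs, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined; those added later are named as such. Each table was tested with limma (empirical Bayes with a mean trend) on log2(normalized count + 1) for genes with a mean of 10 or more, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design assumed 5 control libraries in male gWAT, and 4 were used. Gene lists of metabolic pathways, stress responses, cell types and neighbouring tissues (37 for liver, 41 for gWAT) were tested with limma's camera at a preset correlation of 0.01 where 5 or more members were tested, and again with the correlation estimated for each list. Lists that another tissue's cells would bring are also partly expressed by the studied tissue. The sexes were compared by an interaction term over the 4 groups of a tissue, and by the Pearson correlation across genes of the log2 changes with 100 relabellings of the samples within each sex.

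The named genes were, for each comparison, the 8 largest changes each way among genes past the threshold with a mean of 20 or more; where fewer than 3 passed, the genes of smallest p up to 3; a fixed set of metabolic genes; up to 3 members of up to 6 called lists; and the 3 genes of smallest interaction p per tissue. Predicted genes were counted and not named. Some genes that the rule names are not reported here. Mup11, Hsd3b5, Cyp2a4, Gpnmb, Cpb1 and Acta1 in male liver and Gpnmb in male gWAT were chosen after their values were seen. Gene locations, lengths and GC content came from GENCODE M21 (GRCm38, the assembly of mm10) by symbol: 18066 of 20078 symbols matched a single gene.

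Alternatives covered the pseudocount (0.5 and 5), no filter and a mean of 50 or more, quantile normalization, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, library weights, the replicate number as a block and leaving out each library. Alternatives added after seeing the data left out libraries with transcripts of other tissues or standing apart, removed each library's trend on transcript length and GC content in female gWAT (a spline with 4 degrees of freedom), tested the lists by an exact permutation of their medians over all 126 splits, and tested the lists on the interaction. The code was tested on simulated data with known changes. At a 2-fold change it recovered 82.1% of changed genes in female liver, 47.8% in male liver, 32.8% in female gWAT and 6.0% in male gWAT; at a 4-fold change it recovered 90.9%, 93.9%, 83.3% and 50.0%. For the interaction it recovered 35.1% (liver) and 1.7% (gWAT) at 2-fold, and 86.9% and 43.9% at 4-fold.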

Results

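Liver and gonadal white adipose tissue (gWAT), the fat depot beside the reproductive organs, were profiled in male and female C57BL/6J offspring of fathers exposed to nicotine or to the control treatment, which the table headers call DMSO. Gene expression was measured by 3′-tag RNA sequencing of polyadenylated RNA, which reads a short stretch near the end of each transcript. The labels list 40 samples in 8 groups of 5, and 39 library columns were analysed here, with 4 control columns for male gWAT. All samples carry the same batch number. The libraries held between 1543208 and 2239073 reads assigned to genes. The labels do not say which animals, litters or fathers the samples came from, so p-values measure only the spread between these samples, which may be technical. Values are DESeq2 normalized counts as mean ± SD, log2 changes are nicotine minus control on the log2(normalized count + 1) scale, which understates the change of low genes, and folds are ratios of group means. Adjusted p-values are from limma for genes and from limma's camera test for gene lists.

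The first comparison asked how the liver of daughters differed with the father's exposure. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was the gene with the largest rise among those called. It averaged 105 ± 37.8 normalized counts in controls and 718 ± 336 in the nicotine group (SD, n = 5 each), a 6.81-fold difference (log2 change 2.71, SE 0.24, limma adjusted p = 3.92e-06), and all 5 nicotine libraries lay above all 5 controls. Genes driven by the circadian clock and genes of drug metabolism were also higher, while chaperone, unfolded protein response and immediate early genes were lower, although most members did not pass in each of these lists other than the clock list, and 0 of 31 lists held with an estimated correlation (smallest adjusted p = 0.11). G0s2, an inhibitor of the triglyceride lipase ATGL, fell from 435 ± 83.8 to 106 ± 23.4 (log2 change -2.03, SE 0.14, adjusted p = 1.26e-07); it lies on chromosome 1 at 193272161 to 193273217 on the minus strand of mm10. Efna1, an ephrin ligand, fell from 251 ± 34.9 to 63.7 ± 24.6 (log2 change -2.06, SE 0.22, adjusted p = 1.92e-05). In total 301 of 9173 tested genes passed, 148 higher and 153 lower in the nicotine group. Leaving out single libraries gave 185 to 329 genes. At an unadjusted p below 0.05 there were 1610 genes, against 459 that chance would give. The authors' deposited table lists 316 genes at an adjusted p below 0.05, and 274 of them were also called here, all with the same sign.

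Among the lists called higher, the circadian clock list had the most members that rose when adjusted over all tested genes. Of 17 tested members of the circadian clock list, 9 rose, 1 fell and 7 did not pass, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 3.71e-05, adjusted p = 0.132 with an estimated correlation). Dbp, a transcription factor whose transcription follows the clock, rose from 89.7 ± 22.5 to 207 ± 28.9 (log2 change 1.22, SE 0.15, adjusted p = 8.32e-05). Usp2, a rhythmic deubiquitinase, rose 4.30-fold (29.0 ± 10.8 to 125 ± 46.6, adjusted p = 7.19e-05). Ciart, a clock repressor, rose from 4.80 ± 4.03 to 23.4 ± 10.9 (adjusted p = 0.00551), and Noct, a rhythmic NADP(H) phosphatase, rose 4.28-fold (adjusted p = 5.47e-04).

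Among xenobiotic genes, 4 of 26 tested targets of the nuclear receptors CAR and PXR rose and 22 did not pass, with 12 higher and 0 lower when adjusted over the list alone (camera adjusted p = 4.47e-07, adjusted p = 0.11 with an estimated correlation). Of 13 aryl hydrocarbon receptor and nicotine metabolism genes, 4 rose and 9 did not pass, with 9 higher and 0 lower when adjusted over the list alone (camera adjusted p = 1.10e-05, adjusted p = 0.11 with an estimated correlation). Cyp2a5, the mouse enzyme that oxidizes nicotine, rose from 333 ± 182 to 800 ± 229 (log2 change 1.36, SE 0.26, adjusted p = 0.00535), with 4 of 5 nicotine libraries above all controls. Its reads may be shared with the near-identical Cyp2a4. Cyp1a2 rose 1.77-fold (479 ± 111 to 846 ± 111, adjusted p = 5.86e-04), and Por, the electron donor of microsomal P450 enzymes, rose 1.42-fold (adjusted p = 0.00495). Cyp2c37 and Fmo5 rose 1.49-fold and 1.60-fold. Alas1, the first enzyme of haem synthesis, rose 3.07-fold (adjusted p = 1.64e-04). Cyp3a11, a PXR target, averaged 2128 ± 327 and 2452 ± 252 and did not pass (adjusted p = 0.304).

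The unfolded protein response genes moved the other way, with 5 of 21 lower, 1 higher and 15 not passing, and 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.67e-08, adjusted p = 0.316 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 2809 ± 627 to 1681 ± 125 (log2 change -0.72, SE 0.12, adjusted p = 0.00131). Atf4, a stress-response transcription factor, fell from 209 ± 12.1 to 133 ± 18.3 (adjusted p = 0.00123), and Creld2 fell from 41.5 ± 18.4 to 17.2 ± 2.44 (adjusted p = 0.0128). Of 13 heat shock proteins, 3 fell (Hsph1, Chordc1 and Dnaja1) and 10 did not pass, with 6 lower and 0 higher when adjusted over the list alone (camera adjusted p = 1.45e-04, adjusted p = 0.11 with an estimated correlation). Of 11 immediate early genes 4 fell and 7 did not pass, with 6 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00215, adjusted p = 0.32 with an estimated correlation).

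Smaller shifts were called for other metabolic lists. Of 24 cholesterol synthesis genes 0 passed, also when adjusted over the list alone (median log2 change -0.30, camera adjusted p = 0.00108, adjusted p = 0.605 with an estimated correlation). Mvd averaged 119 ± 47.8 in controls and 61.0 ± 39.2 in the nicotine group (adjusted p = 0.0700), and Srebf2 averaged 66.3 ± 11.8 and 46.9 ± 9.51. Of 25 fatty acid oxidation genes 2 fell and 23 did not pass, with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00413, adjusted p = 0.605 with an estimated correlation). Of 30 urea cycle and amino acid catabolism genes 1 rose and 29 did not pass, with 1 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00206, adjusted p = 0.605 with an estimated correlation). Of 24 interferon response genes 0 passed, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0161, adjusted p = 0.605 with an estimated correlation). Of 14 sinusoidal endothelial genes 2 fell, 1 rose and 11 did not pass, with 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.306 with an estimated correlation). G6pc1, the last enzyme of glucose output, fell from 627 ± 124 to 425 ± 48.9 (adjusted p = 0.0104). Pck1 (6904 ± 1215 and 8106 ± 1085), Cpt1a (842 ± 58.8 and 727 ± 138), Fasn (727 ± 126 and 690 ± 213) and Srebf1 (77.6 ± 17.4 and 116 ± 26.9) did not pass.

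The remaining named genes of the female liver were Errfi1 (2.81-fold), Pfkfb3 (3.93-fold), Akr1c19 (2.92-fold) and Sult2a2 (2.40-fold), which rose, and Snora30, Sowahb, Cyp26b1, Ypel2, Slc25a25 and Bbc3, which fell with log2 changes of -2.39, -1.84, -1.60, -1.52, -1.45 and -1.42. Snora30 encodes a small nucleolar RNA and may share reads with the gene around it. Skeletal muscle markers summed to 283 normalized counts in control library 4 and 456 in nicotine library 5, against 0 to 32.4 in the other libraries. Adipocyte markers summed to 729 to 1496 in controls and 1774 to 2101 in the nicotine group. Without control library 4 and nicotine library 5, 181 genes were called, 91 higher and 90 lower, and Hsph1 (log2 change -0.75, against -0.78 with all libraries; adjusted p = 0.0596), Chordc1 (-0.51, against -0.53; 0.0610), Dnaja1 (-0.39, against -0.40; 0.0726), Cyp26b1 (-1.65, against -1.60; 0.0632), Sult2a2 (1.64 in both; 0.0865) and the sinusoidal endothelial list (0.0687) did not pass. The changes of these genes stayed about the same size with larger standard errors. An exact permutation of each list's median over the 126 splits of the libraries, chosen after seeing the data, gave an adjusted p = 0.0492 (exact p = 0.00794, the smallest possible) for the heat shock, immediate early, CAR and PXR, aryl hydrocarbon receptor and female-biased liver gene lists, the last of which camera did not call (adjusted p = 0.139). The other lists called by camera did not pass this permutation, among them the circadian clock and unfolded protein response lists (exact permutation adjusted p = 0.0615 each).

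**Figure D1:**
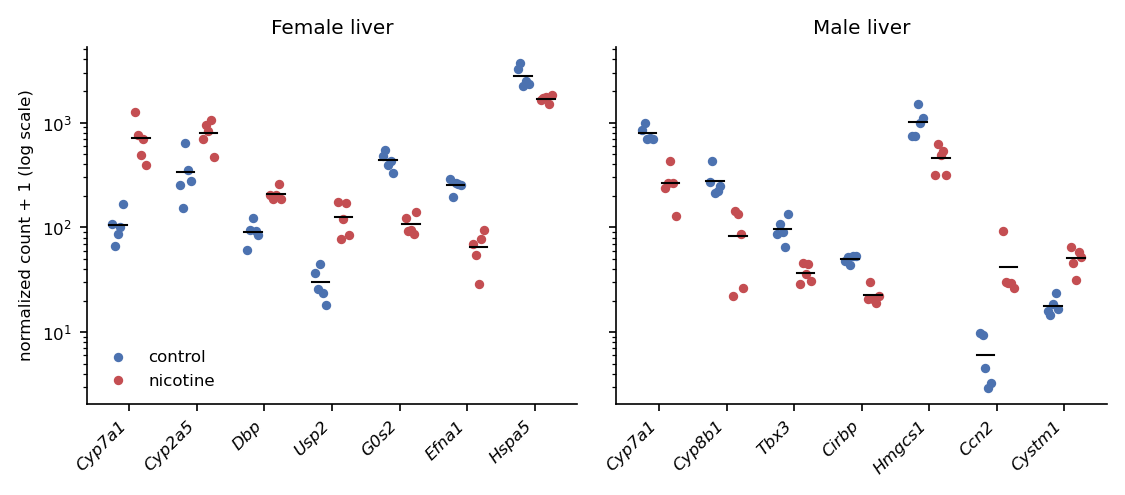
Normalized counts + 1 (log axis) of named genes in each liver library, blue for control and red for nicotine, with black bars at group means (n = 5 each). Cyp7a1 lay higher in all 5 nicotine libraries of the female liver and lower in all 5 of the male liver.

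**Figure D2:**
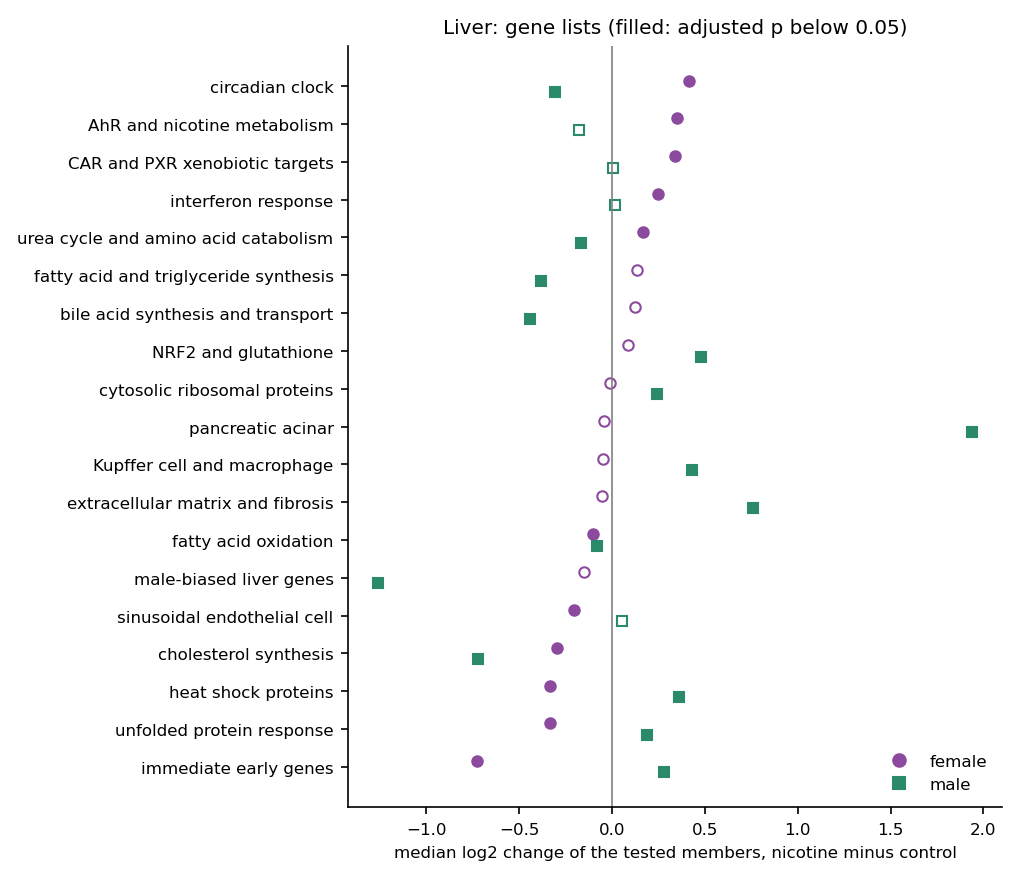
Median log2 change, nicotine minus control, of the tested members of each gene list in female (circles) and male (squares) liver; filled symbols mark a camera adjusted p below 0.05. The circadian clock list had a median of 0.42 in females and -0.31 in males, and the heat shock list -0.33 and 0.36.

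The second comparison put the same question to the liver of sons. Here 5 of 9093 genes passed. Cyp7a1 fell from 789 ± 131 to 263 ± 107 (SD, n = 5 each), the opposite of its change in daughters (log2 change -1.67, SE 0.25, limma adjusted p = 0.0249). Ccn2, a matricellular growth factor also called CTGF, rose from 5.02 ± 3.39 to 40.4 ± 28.4 (log2 change 2.78, SE 0.44, adjusted p = 0.0375; chromosome 10, 24595442 to 24598683, plus strand), and Cystm1 rose 2.94-fold (16.9 ± 3.47 to 49.6 ± 12.9, adjusted p = 0.0249). Tbx3, a T-box transcription factor of pericentral hepatocytes, fell from 95.2 ± 25.3 to 36.0 ± 7.73 (adjusted p = 0.0249). Cirbp, a cold-inducible RNA-binding protein, fell from 49.0 ± 4.38 to 21.6 ± 4.32 (adjusted p = 0.0249). For each of these 5 genes the nicotine libraries did not overlap the controls. At an unadjusted p below 0.05 there were 1322 genes, against 455 that chance would give. The authors' deposited table lists 154 genes, DESeq2 on the recovered reads called 186, and edgeR called 3. Leaving out control library 1, 2, 3 or 5 or nicotine library 1 or 4 left 0 genes called, while leaving out control library 4, nicotine library 3, nicotine library 5 or nicotine library 2 gave 3, 2, 1 and 16.

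Cholesterol and bile acid genes lay lower in the male liver. All 23 tested cholesterol synthesis genes had a lower mean (median log2 change -0.72); 0 passed over all genes, and 12 fell and 0 rose when adjusted over the list alone (camera adjusted p = 3.75e-11, adjusted p = 0.475 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, averaged 1012 ± 310 and 454 ± 138 (adjusted p = 0.113). Dhcr7 averaged 43.1 ± 4.83 and 21.5 ± 8.04 and Hsd17b7 402 ± 46.7 and 204 ± 86.4. Of 20 bile acid synthesis and transport genes 1 fell and 19 did not pass, with 3 lower and 0 higher when adjusted over the list alone (camera adjusted p = 4.95e-07, adjusted p = 0.475 with an estimated correlation). Cyp8b1, which makes cholic acid, averaged 276 ± 88.8 and 81.7 ± 57.7 (adjusted p = 0.122), and Hsd3b7 649 ± 111 and 425 ± 102. Nicotine libraries 1 and 5, which stood apart, carried part of this: without them the log2 change of male liver Cyp8b1 went from -2.09 to -1.18 and that of male liver Hsd17b7 from -1.09 to -0.59. Of 20 fatty acid and triglyceride synthesis genes 0 passed, with 5 lower and 0 higher when adjusted over the list alone (camera adjusted p = 7.53e-05, adjusted p = 0.567 with an estimated correlation). Of 18 clock genes 0 passed, with 3 lower and 0 higher when adjusted over the list alone (camera adjusted p = 2.42e-04, adjusted p = 0.475 with an estimated correlation).

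Heat shock and ribosomal protein genes lay higher in the male liver. Of 14 heat shock proteins 0 passed, with 3 higher and 0 lower when adjusted over the list alone (median log2 change 0.36, camera adjusted p = 7.26e-06, adjusted p = 0.475 with an estimated correlation). Hsp90aa1 averaged 314 ± 72.8 in controls and 495 ± 37.5 in the nicotine group, and Hsph1 64.3 ± 19.6 and 119 ± 18.8, both with an adjusted p = 0.122. Hspa1b, which has a near-identical copy, averaged 20.2 ± 4.74 and 34.0 ± 10.1. Of 75 cytosolic ribosomal protein genes 0 passed, also when adjusted over the list alone, while 73 had a higher mean (median log2 change 0.24, camera adjusted p = 4.09e-10, adjusted p = 0.593 with an estimated correlation); Rpl10, Rpl12 and Rpl17 averaged 1.49-fold, 1.47-fold and 1.56-fold the control. The unfolded protein response list (21 genes, 0 passing, camera adjusted p = 0.0106, adjusted p = 0.693 with an estimated correlation) and the immediate early list (10 genes, 0 passing, 3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00901, adjusted p = 0.475 with an estimated correlation) were shifted upward as well. Plk3, a stress-induced kinase, averaged 42.4 ± 13.3 and 110 ± 38.6 and did not pass (adjusted p = 0.0990).

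Nicotine libraries 1 and 5 stood apart from the other 8 male liver libraries, and several lists moved with them. Of 26 male-biased liver genes 0 passed, also when adjusted over the list alone (median log2 change -1.26, camera adjusted p = 5.82e-07, adjusted p = 0.693 with an estimated correlation). Summed male-biased genes came to 10877 and 19870 normalized counts in nicotine libraries 1 and 5 and to 50572 to 87884 in the others. Elovl3, Susd4 and Cyp4a12a, all male-biased, were named by rule. Elovl3 was at 0 and 1.64 in these libraries and at 76.8 to 218 in the others, and Susd4 at 2.94 and 0 against 37.1 to 101. Mup11, Hsd3b5, Cyp2a4 and Gpnmb were chosen after their values were seen. Mup11, a major urinary protein with near-identical copies, was at 17.7 and 16.4 against 2446 to 13694. Hsd3b5 was at 0 and 0.82 against 210 to 405. The female-biased Cyp2a4 was at 307 and 219 against 7.38 to 21.8. Gpnmb, a gene of lipid-loaded macrophages, was at 51.5 and 45.9 against 0 to 1.77. Of 14 Kupffer cell and macrophage genes 0 passed, with 4 higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.33e-04, adjusted p = 0.567 with an estimated correlation). Kupffer markers summed to 1279 and 1224 in libraries 1 and 5 against 520 to 824. Of 19 extracellular matrix genes 1 rose (Ccn2) and 18 did not pass, with 3 higher and 0 lower when adjusted over the list alone (camera adjusted p = 7.75e-08, adjusted p = 0.475 with an estimated correlation). Col3a1, a fibrillar collagen, was at 272 and 221 in these libraries and at 20.8 to 96.0 in the others, and Col6a3 averaged 22.0 ± 6.56 in controls and 82.8 ± 70.0 in the nicotine group.

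Without nicotine libraries 1 and 5, 6 genes were called, 1 of them among the 5 above, male liver Cyp7a1 (log2 change -1.34, adjusted p = 0.00396); Ccn2 and Cystm1 (log2 change 2.48 and 1.31, adjusted p = 0.0603 each) and Cirbp and Tbx3 (-1.13 and -1.17, adjusted p = 0.0576 each) did not pass with 3 nicotine libraries left. Camera then no longer called the male-biased (adjusted p = 0.806), Kupffer (0.164), fatty acid and triglyceride synthesis (0.187), fatty acid oxidation (0.459), NRF2 and glutathione (0.880), urea cycle (0.757) and immediate early (0.0876) lists. With all libraries these last lists had 0 passing members each: fatty acid oxidation 3 lower and 0 higher when adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.696 with an estimated correlation), NRF2 and glutathione 0 (camera adjusted p = 5.97e-04, adjusted p = 0.585 with an estimated correlation) and urea cycle 0 (camera adjusted p = 0.0102, adjusted p = 0.7 with an estimated correlation). Nicotine library 2 held pancreatic acinar transcripts, 13740 normalized counts summed over 11 markers against 28.7 to 138 elsewhere, and the acinar list was called higher with 0 of 11 members passing (camera adjusted p = 0.0303, adjusted p = 0.7 with an estimated correlation). Nicotine library 4 held skeletal muscle transcripts, 10237 against 0.8 to 11.6. Without libraries 2 and 4, 54 genes were called, 15 higher and 39 lower, among them Cyp8b1, Dhcr7, Hmgcs1, Hsd17b7 and Plk3. The unfolded protein response and fatty acid oxidation lists were then not called (camera adjusted p = 0.255 and 0.0818). This setting keeps nicotine libraries 1, 3 and 5, so libraries 1 and 5, which stood apart, weigh more in it. Cyp8b1 was at 21.3 and 25.4 in libraries 1 and 5 and at 134 in library 3. Hsd17b7 was at 100 and 121 in libraries 1 and 5 and at 264 in library 3. Pck1, Cpt1a, Fasn, Srebf1, G6pc1, Cyp2a5, Cyp3a11 and Fgf21 did not pass in the male liver; Cpt1a averaged 1038 ± 117 and 682 ± 128, and Cyp3a11 1290 ± 185 and 3575 ± 2991, with 8278 and 4827 in nicotine libraries 1 and 5.

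**Figure D3:**
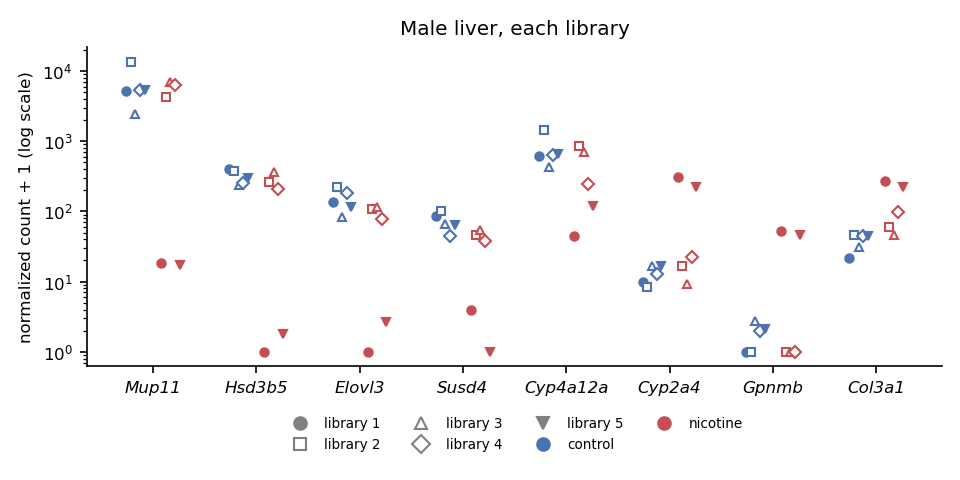
Normalized counts + 1 (log axis) of male-biased, female-biased, macrophage and matrix genes in each male liver library, blue for control and red for nicotine, with a symbol per library number. Libraries 1 and 5 of the nicotine group lay apart from the other 8, for example at 17.7 and 16.4 normalized counts of Mup11 against 2446 to 13694.

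The third comparison asked how gWAT of daughters differed with paternal exposure, and it gave the most called genes of the 4 comparisons. Macrophage, progenitor and matrix genes and ribosomal protein genes were lower in the nicotine group, and fatty acid oxidation, thermogenic and branched-chain amino acid genes were higher. Many members did not pass (9 of 14 thermogenic, 16 of 22 branched-chain amino acid, 38 of 75 ribosomal and 16 of 30 matrix genes), and none of these lists held with an estimated correlation (adjusted p = 0.536 each). Clec3b, a marker of adipose progenitors, fell from 2961 ± 894 to 323 ± 128 (SD, n = 5 each; log2 change -3.24, SE 0.27, limma adjusted p = 2.27e-05; chromosome 9, 123150946 to 123157432, plus strand). Retnla, made by alternatively activated macrophages, fell from 895 ± 166 to 128 ± 58.9 (log2 change -2.91, SE 0.27, adjusted p = 2.99e-05). Ppara, the nuclear receptor that drives fatty acid oxidation, rose from 36.6 ± 23.0 to 204 ± 95.3 (log2 change 2.63, SE 0.47, adjusted p = 0.00149). In all, 2656 of 10532 genes passed, 1303 higher and 1353 lower, and 4027 had an unadjusted p below 0.05, against 527 that chance would give. The authors' deposited table lists 2903 genes, and 2468 were called in both, all with the same sign.

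All 15 tested macrophage genes fell, also when adjusted over the list alone (median log2 change -1.68, camera adjusted p = 2.82e-11, adjusted p = 0.536 with an estimated correlation). C1qc, a complement component made by tissue macrophages, fell from 147 ± 43.4 to 23.1 ± 9.52, and Cd163, the haemoglobin scavenger receptor, from 220 ± 101 to 35.6 ± 15.1. Of 5 monocyte, neutrophil and dendritic cell genes 3 fell and 2 did not pass, with 5 lower when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.536 with an estimated correlation). Of 18 inflammatory cytokines and chemokines 8 fell, 1 rose and 9 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00217, adjusted p = 0.536 with an estimated correlation). Ccl2, which recruits monocytes, averaged 27.3 ± 49.4 and 2.05 ± 3.66 and did not pass (adjusted p = 0.142). Among the genes with the largest falls, Ms4a4a, Fcna and Folr2 are expressed by tissue macrophages and Retnlg by neutrophils; Ms4a4a fell from 92.0 ± 47.8 to 3.25 ± 2.26 and Folr2 from 55.5 ± 22.3 to 4.58 ± 3.204. The lipid-associated macrophage list was not called (3 of 11 lower, 8 not passing, 5 lower when adjusted over the list alone, adjusted p = 0.0807).

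Of 18 progenitor and fibroblast genes 12 fell and 6 did not pass, with 13 lower when adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.536 with an estimated correlation). Pdgfra, the receptor that marks adipocyte progenitors, fell from 184 ± 48.3 to 45.02 ± 18.6, and Mfap5, a microfibril protein, from 123 ± 30.3 to 17.4 ± 12.0. Of 30 extracellular matrix genes 14 fell and 16 did not pass, with 20 lower when adjusted over the list alone (camera adjusted p = 6.51e-07, adjusted p = 0.536 with an estimated correlation), among them Col6a2 (146 ± 23.8 to 49.1 ± 21.6) and Eln, elastin (159 ± 25.9 to 65.0 ± 15.4). Of 15 mesothelial genes 5 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.536 with an estimated correlation), and of 6 erythroid genes 2 fell, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.536 with an estimated correlation). Markers of endothelial cells (median log2 change -0.18, adjusted p = 0.575) and of mural and smooth muscle cells (median -0.20, adjusted p = 0.575) were not called. Of 75 cytosolic ribosomal protein genes 37 fell and 38 did not pass, with 42 lower when adjusted over the list alone (camera adjusted p = 1.57e-12, adjusted p = 0.536 with an estimated correlation); their median log2 change of -0.65 went to -0.21 when each library's trend on transcript length and GC content was removed. Rpl37a fell from 1750 ± 386 to 435 ± 108, Rpl41 from 604 ± 144 to 179 ± 34.0 and Rpl28 from 450 ± 96.1 to 149 ± 35.4; ribosomal protein genes have processed copies that can share their reads.

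Of 23 fatty acid oxidation genes 15 rose, 2 fell and 6 did not pass, with 17 higher and 3 lower when adjusted over the list alone (median log2 change 1.05, camera adjusted p = 4.23e-06, adjusted p = 0.536 with an estimated correlation). Hadhb, a subunit of the mitochondrial trifunctional protein, rose from 150 ± 26.2 to 501 ± 230, Acadl, the long-chain acyl-CoA dehydrogenase, from 399 ± 95.0 to 943 ± 240, and Etfa, an electron carrier, from 142 ± 13.5 to 299 ± 59.9. Of 14 thermogenic genes 5 rose and 9 did not pass, with 9 higher when adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.536 with an estimated correlation). Ppargc1b, a coactivator of mitochondrial genes, rose from 37.3 ± 16.5 to 180 ± 41.8, while Ucp1, the uncoupling protein of brown fat, averaged 117 ± 83.2 and 654 ± 533 and did not pass (adjusted p = 0.0953). Of 22 branched-chain amino acid catabolism genes 6 rose and 16 did not pass, with 8 higher when adjusted over the list alone (camera adjusted p = 9.10e-05, adjusted p = 0.536 with an estimated correlation), among them Bckdha (54.2 ± 20.5 to 139 ± 36.0) and Dbt. Of 20 fatty acid and triglyceride synthesis genes 8 rose and 12 did not pass, with 10 higher when adjusted over the list alone (camera adjusted p = 4.21e-04, adjusted p = 0.599 with an estimated correlation). Of 20 cholesterol synthesis genes 6 rose, 1 fell and 13 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.599 with an estimated correlation). Of 16 clock genes 6 rose and 10 did not pass, with 7 higher when adjusted over the list alone (camera adjusted p = 0.00195, adjusted p = 0.536 with an estimated correlation). Of 21 lipolysis genes 4 rose and 17 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.76 with an estimated correlation).

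Adipokines and adipocyte identity genes were not called as a list (4 of 25 higher and 21 not passing, 4 higher when adjusted over the list alone, adjusted p = 0.335). Adipoq (6626 ± 1943 and 5072 ± 1515), Lep (48.4 ± 16.2 and 66.3 ± 40.2), Retn (925 ± 216 and 894 ± 267), Pnpla2, Pparg and Slc2a4 did not pass. Snora81, a small nucleolar RNA that may share reads with the gene around it, had the largest rise, from 49.99 ± 14.5 to 1355 ± 860. Ccm2l, Syne3, Pank1, Jund and Lrrc39 also rose, by 2.41, 2.41, 2.35, 2.35 and 2.28 on the log2 scale. Col6a4, Islr2, S100g and Rprm fell with log2 changes of -3.94, -3.71, -3.69 and -3.69, and S100g, a calcium-binding protein of uterus and gut, was at 183 in control library 4 and at 0 to 1.15 in the nicotine libraries. Of 8 mitochondrially encoded transcripts 3 rose and 5 did not pass, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.6 with an estimated correlation). The mitochondrial ribosomal RNA mt-Rnr2 took 5.23% to 7.75% of the reads of control libraries and 12.5% to 23.1% of those of nicotine libraries. Oviduct and uterus markers summed to 6620 and 2856 in control libraries 4 and 5 against 313 to 806 elsewhere, and skeletal muscle markers to 36121 in control library 2 against 67.3 to 1990. Across genes, which are not independent replicates, the log2 change rose with transcript length (Spearman's rho 0.212) and fell with GC content (rho -0.208).

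Without control libraries 4 and 5, 1603 genes were called, 1513 of them among the 2656, and without control libraries 2, 4 and 5 and nicotine library 1 there were 1216, 1116 of them among the 2656. In both settings the cytokine, mesothelial, lipolysis and mitochondrially encoded lists were no longer called (adjusted p = 0.287, 0.158, 0.128 and 0.128 in the first), Lrrc39 (0.0569) and Rprm (0.0736) did not pass in the first, and the macrophage, progenitor, matrix, ribosomal and fatty acid oxidation lists stayed called.

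**Figure D4:**
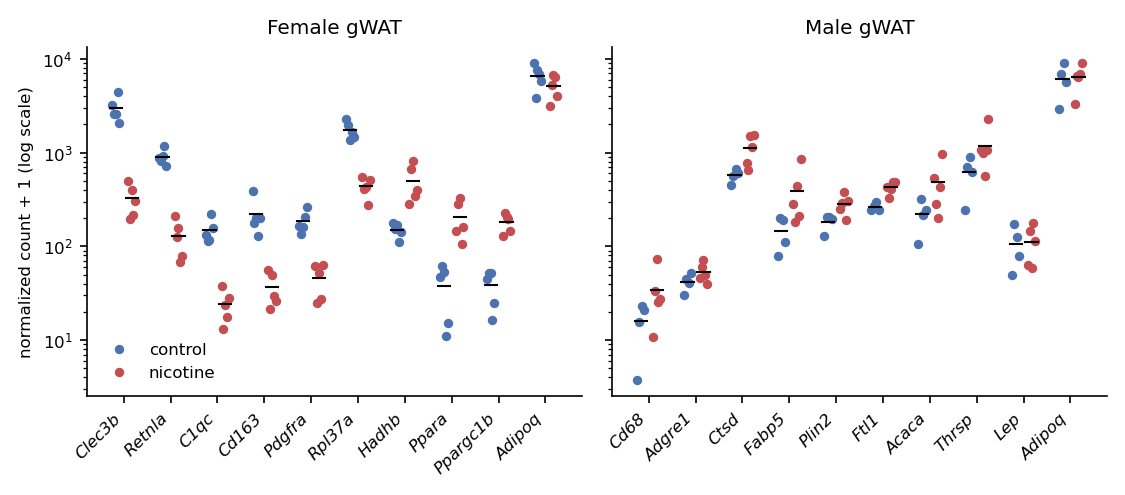
Normalized counts + 1 (log axis) of named genes in each gWAT library, blue for control and red for nicotine, with black bars at group means (n = 5 and 5 in females, 4 and 5 in males). In females Clec3b, Retnla and C1qc lay lower and Hadhb, Ppara and Ppargc1b higher in all 5 nicotine libraries than in any control.

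**Figure D5:**
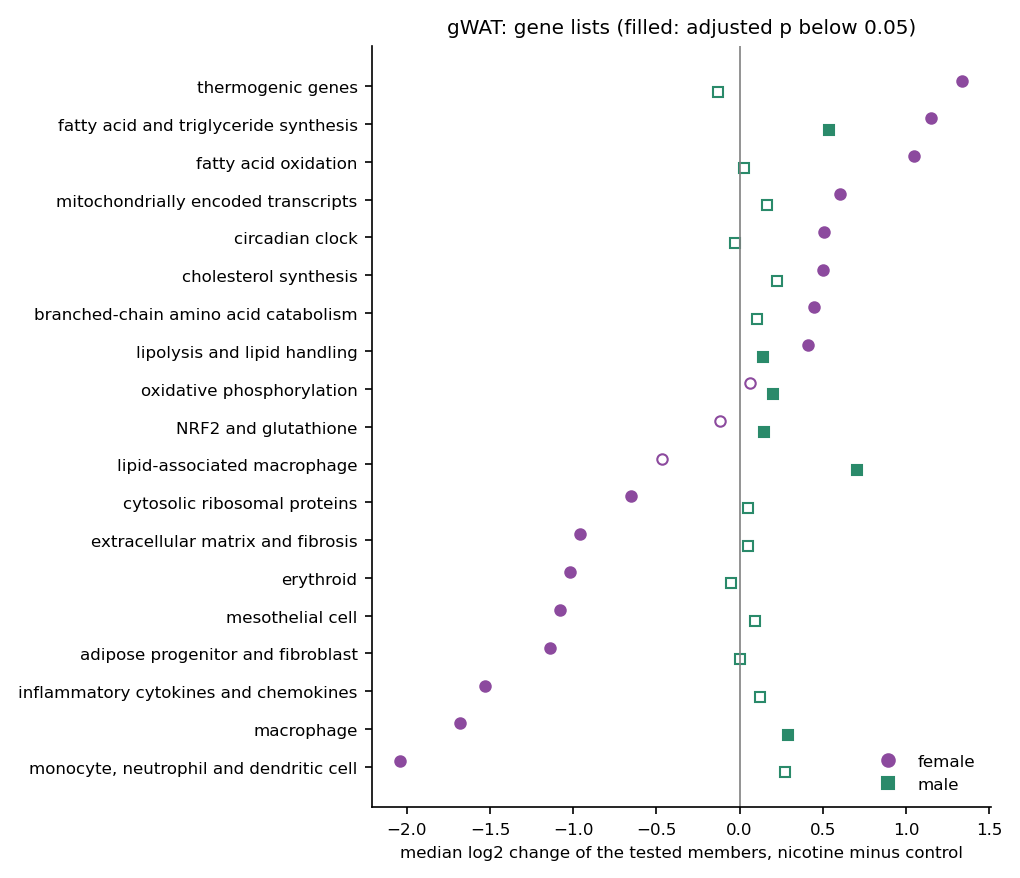
Median log2 change, nicotine minus control, of the tested members of each gene list in female (circles) and male (squares) gWAT; filled symbols mark a camera adjusted p below 0.05. The macrophage list had a median of -1.68 in females and 0.29 in males.

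The fourth comparison, gWAT of sons, had 4 control and 5 nicotine libraries, and 0 of 11210 genes passed. The authors' deposited table also lists 0, with a smallest adjusted p of 0.583. There were 182 genes at an unadjusted p below 0.05 in limma against 560 that chance would give, 197 in edgeR and 185 in DESeq2, which called 0 genes each. The genes of smallest p were Ftl1, the ferritin light chain (262 ± 24.5 in 4 controls and 426 ± 65.8 in 5 nicotine libraries), Ackr4 (41.02 ± 10.5 and 74.9 ± 19.4) and Reep6 (22.3 ± 8.01 and 42.8 ± 9.97) among those higher, and Tipin (94.3 ± 17.9 and 59.8 ± 6.37), Cpeb3 (72.1 ± 13.0 and 47.9 ± 3.34) and Snora81 (51.6 ± 24.4 and 16.8 ± 16.0) among those lower. All had an adjusted p = 1.00 (limma).

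Camera called 6 of 36 lists in male gWAT, each shifted upward with 0 members passing, also when adjusted over the list alone, and each with an adjusted p = 0.963 with an estimated correlation. They were oxidative phosphorylation (42 genes, median log2 change 0.20, camera adjusted p = 3.84e-06), fatty acid and triglyceride synthesis (20 genes, 0.54, 1.08e-05), lipid-associated macrophages (16 genes, 0.71, 1.13e-05), macrophages (16 genes, 0.29, 0.0131), lipolysis (21 genes, 0.14, 0.0323) and NRF2 and glutathione (15 genes, 0.15, 0.0343). Ndufa4, a subunit of the respiratory chain, averaged 151 ± 41.2 and 206 ± 33.2, Ndufa8 49.5 ± 5.37 and 67.1 ± 17.5, and Ndufb7 115 ± 12.9 and 160 ± 62.4. Acaca, which makes malonyl-CoA, averaged 220 ± 88.9 and 479 ± 298, Thrsp 616 ± 271 and 1186 ± 644, and Gpam 297 ± 99.3 and 424 ± 94.1. Fabp5, a fatty acid-binding protein, averaged 145 ± 60.2 and 391 ± 275, Plin2, a lipid droplet protein, 183 ± 37.6 and 280 ± 69.3, and Ctsd, a lysosomal protease, 573 ± 92.5 and 1118 ± 404. The macrophage genes Cd68, Adgre1 and Mpeg1 averaged 14.8 ± 8.65 and 33.1 ± 23.6, 40.8 ± 8.94 and 52.4 ± 12.2, and 19.2 ± 3.14 and 47.5 ± 49.5. Adrb1, Gsr, Gsta3 and Srxn1 averaged 2.49-fold, 1.70-fold, 1.59-fold and 1.49-fold the control. Adipoq (6106 ± 2534 and 6427 ± 2063), Lep (106 ± 54.8 and 111 ± 51.5), Retn, Pnpla2, Pparg, Slc2a4 and Ccl2 (11.1 ± 5.11 and 11.0 ± 10.2) did not pass. Epididymis markers summed to 110433 in control library 1 and 87359 in nicotine library 1. The other controls held 280 to 3708 and the other nicotine libraries 1485 to 11461. Without control library 1 and nicotine library 1, 0 genes were called and the lipolysis and NRF2 lists were not (camera adjusted p = 0.146 and 0.103). That setting does not remove the epididymis markers of the remaining libraries.

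The changes of the sexes were compared directly by an interaction test. In liver 136 of 8699 genes changed differently, 61 with a change larger in males and 75 larger in females (as signed values), and 129 of them had opposite signs. Selection for a difference between the sexes favours opposite signs, so this count alone does not show opposite responses. Leaving out single libraries gave 71 to 280 genes. Cyp7a1 had the smallest p, with a male minus female difference of -4.38 (SE 0.40, limma adjusted p = 1.00e-06); it lies on chromosome 4 at 6265612 to 6275633 on the minus strand of mm10. Il6ra, the interleukin 6 receptor, rose from 26.0 ± 3.22 to 55.3 ± 10.6 in daughters and averaged 37.9 ± 3.00 and 21.3 ± 4.68 in sons (difference -1.87, adjusted p = 1.77e-04). Nedd4l, a ubiquitin ligase, fell from 116 ± 14.7 to 60.9 ± 8.93 in daughters and averaged 44.7 ± 6.10 and 82.2 ± 20.1 in sons (difference 1.76, adjusted p = 2.19e-04). Applied to the interaction, camera called 17 of 31 lists, and 3 of them also with an estimated correlation: the circadian clock (median log2 change 0.42 in females and -0.28 in males, adjusted p = 0.0345 with an estimated correlation), heat shock proteins (-0.33 and 0.35, adjusted p = 0.048 with an estimated correlation) and aryl hydrocarbon receptor and nicotine metabolism genes (0.35 and -0.18, adjusted p = 0.048 with an estimated correlation). These list tests of the interaction were added after seeing the data and were not repeated with any library left out. In sons they include nicotine libraries 1 and 5, which stood apart, and 2 and 4, which held transcripts of other tissues. Across the 8699 genes, which are not independent, the correlation of male and female log2 changes was 0.006 (Pearson, permutation p = 0.911 over 100 relabellings; Spearman's rho -0.004).

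In gWAT 891 of 10042 genes changed differently between the sexes, 445 with a larger signed change in males and 446 in females, and 768 had opposite signs. Opposite signs are again favoured by the selection, and 0 genes passed in male gWAT, so an opposite response in sons is not shown. Leaving out 1 library gave 448 to 1122 genes. Ms4a4a (difference 4.88, limma adjusted p = 1.66e-04) fell in daughters and averaged 82.1 ± 39.2 and 113 ± 56.6 in sons. Cpeb3 (-2.20, adjusted p = 1.66e-04) rose from 33.2 ± 8.31 to 103 ± 12.2 in daughters, and Ftl1 (2.43, adjusted p = 1.99e-04) fell from 319 ± 49.2 to 99.0 ± 41.2. Camera called 12 of 31 lists for the interaction, with 0 called when the correlation was estimated; the macrophage list (median log2 change -1.68 in females and 0.27 in males, 11 of 15 members called) had an adjusted p = 0.536 with an estimated correlation. The correlation of male and female changes across genes was -0.13 (Pearson, permutation p = 0.297 over 100 relabellings; Spearman's rho -0.14).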

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

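The tests of cell share, transcript length and GC content, nuclear RNA, sample identity, carry-over and collection time were chosen only after the results they measure were seen, while the glucocorticoid test and the splits of the samples were chosen before. Standard errors of list medians in these tests came from resampling the list members. They measure the spread between genes, which are not independent, and not the spread between samples.

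A single library lay far from the others of its group, by Dixon's gap test, in 30 of 280 groups of named genes, where chance gives about 1 in 20 groups, or 14. In female liver these were Atf4 at 188 (control library 3, lowest), Cyp1a2 at 672, Sult2a2 at 84.4 (both control library 3, highest), Srebf2 at 46.0 (control library 3, lowest), Cyp26b1 at 39.7 and Fmo5 at 899 (nicotine library 3, highest), Cyp3a11 at 1566 (control library 1, lowest), Dbp at 256 (nicotine library 4, highest) and Errfi1 at 821 (control library 2, highest). In male liver they were Ccn2 at 91.2 (nicotine library 1, highest), Cyp4a12a at 1457, Cyp8b1 at 430 and Hsp90aa1 at 441 (control library 2, highest) and Pck1 at 5163 (control library 5, lowest). In female gWAT they were Ccl2 at 115, Retnlg at 155 and S100g at 183 (control library 4, highest), Cd163 at 392 and Ms4a4a at 174 (control library 1, highest), Islr2 at 17.4 (control library 5, lowest), and among nicotine libraries Ccl2 at 8.44 (library 5), Ms4a4a at 7.27 (library 3), Col6a4 at 4.59, Rprm at 12.6 and S100g at 1.15 (library 1). In male gWAT they were Mpeg1 at 135 (nicotine library 3), Ndufb7 at 271 and Thrsp at 2279 (nicotine library 5), Snora81 at 44.2 (nicotine library 2) and Srxn1 at 107 (control library 1), each the highest.

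Named genes whose change differed between the sexes by the interaction test (male minus female log2 change in brackets) numbered 20 in liver: Akr1c19 (-1.39), Alas1 (-1.56), Atf4 (0.84), Chordc1 (0.92), Ciart (-3.09), Cirbp (-1.11), Cyp1a2 (-1.81), Cyp7a1 (-4.38), Dbp (-1.499), Efna1 (1.82), Errfi1 (-1.82), G0s2 (1.42), Hsp90aa1 (1.14), Hspa5 (1.27), Hsph1 (1.69), Il6ra (-1.87), Nedd4l (1.76), Tbx3 (-1.51), Usp2 (-2.51) and Ypel2 (1.85). In gWAT there were 29: Adgre1 (1.75), C1qc (3.10), Ccm2l (-2.34), Cd163 (3.05), Clec3b (3.14), Col6a2 (2.07), Cpeb3 (-2.20), Ctsd (1.45), Dbt (-1.08), Etfa (-1.02), Fcna (3.63), Folr2 (3.58), Ftl1 (2.43), Hadhb (-1.57), Islr2 (3.72), Jund (-2.64), Mfap5 (3.22), Mpeg1 (2.11), Ms4a4a (4.88), Pank1 (-2.60), Pdgfra (2.13), Ppara (-3.20), Ppargc1b (-2.80), Retnla (2.94), Rpl28 (2.02), Rpl37a (2.31), Rpl41 (1.89), Snora81 (-6.29) and Syne3 (-2.73).

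In female gWAT, macrophage, stromal and ribosomal protein genes were lower and fatty acid oxidation genes higher in the nicotine group, although none of these lists held with an estimated correlation (adjusted p = 0.536 each), and 38 of 75 ribosomal protein genes did not pass. An equally lower share of every cell type other than adipocytes is argued against by endothelial and mural genes. Their median log2 change lay 1.503 (SE 0.26 between genes) above that of macrophage genes. Summed macrophage markers did not overlap between the groups (2387 to 4104 in controls, 514 to 1101 with nicotine). Endothelial sums did (18164 to 37400 and 17524 to 25870), but only through control library 2, which held skeletal muscle transcripts. The other controls ran from 30483 to 37400. Mural and smooth muscle sums were 1969 to 2194 in nicotine libraries 2, 3 and 4, below the lowest control (2212). They were 8461 and 4653 in nicotine libraries 1 and 5. The contrast with macrophage genes was not repeated without these libraries. A smaller fall of endothelial or mural cells is not argued against. With each library's trend on transcript length and GC content removed, 2192 of 9712 genes were called (1254 higher, 938 lower) against 2427 of the same genes before, with 1864 in both, and the macrophage median stayed at -1.68, which argues against such a bias as the whole cause, although 11 of 2445 reported calls had the opposite sign and the ribosomal median moved from -0.65 to -0.21. A larger share of nuclear RNA cannot be told apart from no such share, since 13 nuclear RNAs went both ways (median log2 change -0.076, SE 0.18). Of these, 5 were above 0, with Snora81 highest at 4.40. Without Malat1 and Snora81, whose values had been seen, the median was -0.20 (SE 0.19), with 3 of 11 above 0. The make-up of the libraries differed between the groups too. The 10 most-read genes took 34.2% to 46.2% of the reads of nicotine libraries and 19.3% to 27.5% of those of controls. Genes with a read numbered 14632 to 15927 with nicotine and 15877 to 16190 in controls. Whether this difference is technical was not tested. A lower share of macrophages and progenitors alone, a difference in dissection and an effect of the father's exposure stay open, untested.

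In male liver, male-biased genes were low and macrophage and matrix genes high in nicotine libraries 1 and 5. Female or mislabelled female samples are argued against by Y-linked genes, which summed to 408.3 and 455.3 in these libraries. The other male liver libraries ran from 395.5 to 482.4 (SD 28.7). Xist was at 3.7 and 0 normalized counts in libraries 1 and 5 and at 0 to 19.7 in the others. Carry-over of pancreas or muscle is argued against as well, since 0 of these 2 libraries exceeded every control in either marker sum. A disease or hormonal state of the animals and an effect of the father's exposure stay open, untested.

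In liver, Cyp7a1 rose in daughters and fell in sons. The change of the clock list differed between the sexes (camera interaction adjusted p = 0.0345 with an estimated correlation), although 0 of 18 clock genes passed in sons. Its median log2 change was 0.42 in daughters and -0.28 in sons. This list test of the interaction was not repeated with any library left out. A difference in the time of collection between groups cannot be told apart from other causes. Clock outputs driven by E-boxes minus genes driven by ROR elements differed by 1.40 (SE 0.31) in females and -0.39 (SE 0.14) in males, but the ROR genes opposed the outputs in females alone (median -0.65, against -0.085 in males, where outputs were at -0.47). The ROR medians rest on 3 genes in each liver, Clock, Nfil3 and Cry1, at -0.65, -0.83 and -0.33 in females. Of these only Clock passed in females (limma adjusted p = 0.0263), and an SE from 3 genes is itself uncertain. The same difference of outputs minus ROR genes was 1.04 (SE 0.56) in female gWAT, with 3 ROR genes. It was -0.055 (SE 0.18) in male gWAT, with 2 ROR genes. The times of collection are not given in the sources used here. A glucocorticoid response cannot be told apart from no such response, since induced genes went both ways (median male minus female difference 0.074, SE 0.41). Feeding state and an effect of the father's exposure stay open, untested.

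Chance as the origin of the gene counts was tested over 100 of the 126 splits of the libraries, the real 1 included. In 3 comparisons no other drawn split gave as many genes, which argues against chance. Female liver had 301 against at most 66, male liver 5 against 3 and female gWAT 2656 against 15. Leaving out any of several single libraries took the male liver calls to 0. Splits treat samples as exchangeable, which cannot be assured while fathers and litters are unknown. For male gWAT the test could not decide, because 0 genes were called and every split must give at least as many. Of the other splits 92 gave 0 genes and the highest gave 267. What set that split apart was not tested. Chance could not be excluded for the number of lists: 11 in female liver (highest other 19, 19 splits as large), 15 in male liver (23, 38 splits), 16 in female gWAT (24, 26 splits) and 6 in male gWAT (24, 92 splits). For the differences between the sexes no other relabelling gave as many genes, with 136 in liver against at most 6 and 891 in gWAT against at most 332. Relabelling breaks the link with exposure in both sexes, so its reference is no change in either sex, not equal changes in both. These counts therefore cannot by themselves test whether the sexes differ. For the correlations chance could not be excluded: 0.006 in liver against -0.19 (93 relabellings as far from 0) and -0.13 in gWAT against -0.29 (29 relabellings). These relabellings were drawn separately from those behind the relabelling p of 0.911 and 0.297 in the report, where gWAT reached 0.355.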

How the results depend on the processing

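The alternatives that left out chosen libraries, corrected for length and GC content, or permuted list medians, and the list tests of the interaction, were chosen after seeing the data. Over all alternatives, 2955 values of named genes kept direction and side of the threshold, 29 newly passed, 81 no longer passed and 25 changed sign. For lists, 639 were kept, 75 newly passed and 110 no longer passed. For counts and correlations, 198 were kept, 6 were larger and 39 smaller. A count was kept if within 1.5 times the reported value. A correlation was kept if it moved by less than the SD of its relabelled values (0.063 in liver, 0.12 in gWAT). The liver correlation was thus kept although it ran from -0.042 to 0.050 over single libraries left out. The cause was not tested for any change below, beyond the smaller number of libraries or genes where a setting has it.

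Female liver calls went from 301 to 181 without control library 4 and nicotine library 5 (164 shared), and to 185 (without control library 5), 195 (without nicotine library 4) and at most 329 when single libraries were left out. Male liver calls went from 5 to 0 at a mean of 50 or more, 3 with edgeR (1 higher, 2 lower), 186 with DESeq2, 4 with quantile normalization (1 higher, 3 lower), 54 without nicotine libraries 2 and 4 (all 5 shared), and to between 0 and 16 when single libraries were left out: 0 without control library 1, 2, 3 or 5 or nicotine library 1 or 4, 3 without control library 4, 2 without nicotine library 3, 1 without nicotine library 5 and 16 without nicotine library 2. Female gWAT calls went from 2656 to 1603 without control libraries 4 and 5 and 1216 without control libraries 2, 4 and 5 and nicotine library 1, and ranged from 1954 to 2768 over single libraries. Male gWAT stayed at 0 genes in all settings run; its lists went from 6 to between 4 (without nicotine library 5) and 12 (without control library 1). Differences between the sexes went from 136 to between 71 and 280 genes in liver: 75, 90 and 86 without female control library 1, 2 or 5, 90 and 71 without female nicotine library 1 or 4, 73 without male control library 1, and 88, 259 and 280 without male nicotine library 1, 2 or 3. In gWAT they went from 891 to between 448 and 1122: 577, 586 and 536 without female control library 4 or nicotine library 2 or 4, and 524 and 448 without male control library 3 or 4.

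Lists called by exact permutation numbered 5 in female liver, 0 in male liver, 0 in female gWAT and 0 in male gWAT; at an unadjusted exact p below 0.05 they numbered 9, 2, 14 and 2, and 5, 0, 3 and 0 had the largest median of all 126 splits, the smallest possible p of 0.00794. With an estimated correlation 0 lists were called in each comparison. For the interaction, 3 in liver and 0 in gWAT held with an estimated correlation. No list can have an exact p below 0.00794, so after adjustment over 31 to 36 lists one passes only if several reach it together. In female gWAT the macrophage, progenitor and fatty acid oxidation lists reached it and had an exact permutation adjusted p = 0.081. For these 3 lists the permutation therefore could not decide.

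Named genes that changed sign had not passed. Over single libraries left out, female liver Fasn ranged from -0.24 to 0.0035, male liver Srebf1 from -0.39 to 0.043, female gWAT Pnpla2 from -0.36 to 0.070, Retn from -0.20 to 0.13 and Lep from -0.041 to 0.63. In male gWAT Ccl2 ranged from -0.55 to 0.0021, Adipoq from -0.21 to 0.34, Lep from -0.24 to 0.37, Retn from -0.039 to 0.48 and Pparg from -0.36 to 0.089. Male liver Mup11 was at 0.057 without nicotine libraries 1 and 5. With the length and GC correction female gWAT Pnpla2 was at 0.034 and Retn at 0.19. In male gWAT Ccl2 was at 0.011 with edgeR, Adipoq, Lep and Retn at -0.11, -0.29 and -0.034 with library weights, and Lep at -0.067 without control library 1 and nicotine library 1.

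With the replicate number as a block (replicate block), 341 genes were called in female liver, 0 in male liver, 2011 in female gWAT and 95 for the liver difference between the sexes. The numbers are only shared between groups: over 15 same-numbered pairs of a control and a nicotine sample the correlation ran from -0.277 to 0.173, 1 pair above 0.1, and 3 of 30 samples were best matched by their own number. No paired analysis was possible because the control columns of male gWAT carry no sample number; this holds for male gWAT and the gWAT difference between the sexes. Small changes were mostly missed in the self-test, which recovered 34.3% of 1.5-fold changes in female liver, 6.0% in male liver and 0% in gWAT of both sexes. Depth was not varied, so its part and that of the spread between samples were not separated. The self-test changed 66 or 67 genes at each fold within a table, while 25.2% of tested genes were called in female gWAT. Adjustment is stricter where few genes change, so the 0% need not hold for the female gWAT data.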

Other observations

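Nicotine library 4 of male gWAT held little mt-Rnr2 (0.348% of its reads, against 2.58% to 5.29% in the other 8 libraries) and little Malat1 (0.042%, against 0.325% to 1.00%), while Neat1, another nuclear RNA, was at 0.232%, against 0.113% to 0.251%. Gpnmb, chosen after its values were seen, was at 2770 normalized counts in nicotine library 3 of male gWAT and at 14.7 to 105 in the others. In female gWAT, Xist ran from 1332 to 1782 in controls and from 1031 to 1192 in the nicotine group, and the mural and smooth muscle markers were highest in nicotine library 1 (8461). In male liver, Cpb1, a pancreatic protease, was at 1985 in nicotine library 2, and Acta1, skeletal muscle actin, at 2354 in nicotine library 4; both were chosen after their values were seen.

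Of the genes called in females, 134 had the same sign and 158 the opposite sign in male liver, and 1023 had the same and 1569 the opposite sign in male gWAT. The log2 change was correlated with transcript length and GC content in male gWAT as well (Spearman's rho -0.233 and 0.197), with signs opposite to female gWAT, and less so in female liver (-0.020 and -0.041) and male liver (-0.151 and 0.050).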
